A study of Mus musculus with 4 samples.

How the data were processed

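The samples were CD45-positive cells sorted from dorsal skin around an infected implant, taken 2 or 10 days post infection from C57Bl6 mice. Each day had 1 messenger RNA library and 1 library of hashtags, which are antibody-borne barcodes that mark the mouse a cell came from. Per the labels, hashed cells of 4 mice per day were pooled in equal numbers. The deposited matrices hold raw counts of unique molecular identifiers (UMIs), per the file headers written by software version 3.0.2, and whole numbers in the values bore this out. The deposited hashtag files also hold raw counts, for barcodes with at least 200 detected genes. Per the submitters' processing notes, Cell Ranger and Seurat 2.3 were used with build mm10. The aligner settings and the annotation release were not given in the sources used here. The matrices list 6794880 barcodes and 32285 genes each, and 32158 of the gene identifiers (99.6%) were found in the GENCODE annotation of GRCm38 used for positions.

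Cells were barcodes in the hashtag file with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs, which left 6397 barcodes at day 2 and 3573 at day 10. Seurat 5.3.0 (HTODemux, positive quantile 0.99) set a limit for each hashtag. A cell was given to the mouse of the single hashtag over its own limit, which left out 1078 and 365 barcodes with several hashtags and 25 and 293 with none. Scrublet called 0 and 1 doublets, where 501 and 363 doublets within a mouse were expected (9.46% and 12.5% of kept cells), so that same-mouse doublets remain. The 5294 and 2914 kept cells were log-normalised to 10000 counts and clustered over both days with scanpy 1.11.5 (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1.0, seed 0). Clusters were named by fixed marker lists. The rule for naming clusters was revised after the clusters had been seen, and so was the assignment of a mouse, for which Seurat's own label was kept as an alternative.

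Counts were summed per mouse and class for mice with at least 20 cells of the class. Sums were compared between the days with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F-test, Benjamini-Hochberg threshold 0.05), with R 4.3.3. Fold changes are given on the log2 scale as day 10 minus day 2 with a standard error (SE), and levels as CPM, the usual scaling of a class's summed counts to a common total per mouse. A positive value means higher at day 10. The plan asked for 3 mice per day with 20 cells. Monocytes and macrophages had 3 mice at day 2 and 2 at day 10, so that their test was added after seeing the data. The difference between the day effects of both classes was tested as a class-by-day interaction with mouse as a block. Shares of cell classes and of neutrophil states per mouse were compared by two-sided exact permutation tests. The states came from a second clustering of neutrophils at resolution 0.5 that left out the genes past the threshold between the days.

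The main comparisons, the 27 gene lists, the cell type markers, the alternatives tried and the rule for named genes were fixed before the data were examined, apart from those named as added or chosen later. The rule took, per class, the 10 genes with the largest change in each direction. These had to have an adjusted p under 0.05, a mean log2 CPM of at least 5 and every mouse of 1 day above every mouse of the other. Predicted, mitochondrial, ribosomal protein and erythroid genes were left out of this part. From each list the rule took the 3 most abundant members past the threshold and the most abundant one that was not, and it took the cell type markers where shares or free RNA are described. Genes named outside the rule were chosen after their values were seen. Lists were tested against all other genes with camera in limma 3.58.1 (preset correlation 0.01, voom weights, Benjamini-Hochberg over the lists) and again with an estimated correlation. Of the listed symbols, Mx1 and Clec7a were not among the genes of the files.

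Free RNA was read from barcodes with at most 100 UMIs. The largest share of a class that free RNA can take was bounded by markers of other cell types. For the monocyte and macrophage bound, S100a8, S100a9 and Csf3r were left out of the neutrophil markers after seeing their values. The alternatives were DESeq2 1.42.0 as the test and its size factors in edgeR, no filter on low counts, other UMI and mitochondrial limits, and a rule that asks the first hashtag for 80% of a cell's hashtag counts. Others were subtraction of free RNA, cells thinned to 500 UMIs, another clustering resolution, hashtag number as a block, and each mouse left out in turn. With 1 day 10 mouse left out, the lone mouse is assumed to vary like the others. On simulated data built on the neutrophil sums, with 200 of 7122 genes changed, the test recovered 18% of 2-fold and 74% of 4-fold changes with 1 false call. For monocytes and macrophages, with 200 of 5282 changed, it recovered 39% and 91% with 8 false calls. More genes passed in the real data (1381 and 730), and the adjusted threshold depends on that share, so that these rates may not carry over. Intervals of single shares are exact Clopper-Pearson 95% intervals, and the upper limit for a count of 0 is 3 counts of the total. Both cover counting error only. T, NK, dendritic, B cells and basophils had too few cells per mouse at day 2 for a gene test, and barcodes with no or several hashtags were left out of all comparisons.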

Results

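Leukocytes were profiled from skin around an implant infected with a Staphylococcus aureus biofilm, 2 and 10 days post infection. The series asks how the phase of infection shapes the neutrophils of the host. The day 2 library held 13834668 UMIs and the day 10 library 14624652, with medians of 1681 and 2951 UMIs per barcode listed in the hashtag files. Hashtag counts averaged 1054 per barcode at day 2 and 98.6 at day 10. After filtering, the day 2 mice had 1934, 490, 2065 and 805 cells, and the day 10 mice had 10, 11, 1603 and 1290. The first 2 mice of day 10 therefore had too few cells for any gene test, and gene comparisons used day 10 mice 3 and 4. The barcodes called for these 2 hashtags held medians of 54 and 39.5 counts of their own hashtag, where barcodes of other mice held 9. Seurat labelled 28 and 23 barcodes with them, of which 18 and 11 lay under the limit of that hashtag. Hashing of these mice may therefore have failed, and the 10 and 11 cells may not stand for them. Barcodes called for day 10 mice 3 and 4 held medians of 87 and 27 of their own hashtag, where barcodes of other mice held 1. The limit of both hashtags was 13. The rule on the first hashtag's share of a cell's hashtag counts called 985 and 182 barcodes, where 1691 and 1351 were called as reported. The assignment of day 10 mouse 4 is therefore less secure than that of day 10 mouse 3. If cells of day 10 mice 1 and 2 were counted under hashtags 3 or 4, the sums of day 10 mice 3 and 4 mix mice. Their spread, which enters the SE and adjusted p of the gene, list and interaction tests, would then not be that between mice. Each day was 1 capture and 1 library, so that day and library cannot be told apart in any comparison.

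Neutrophils made up most of the sorted cells on both days, with monocytes and macrophages next and few lymphocytes. Neutrophils, named by markers such as the calcium-binding alarmins S100a8 and S100a9, were 93.1% ± 2.11 of the cells of a mouse at day 2 and 93.3% ± 7.79 at day 10 (mean ± SD, n = 4 and 4 mice; exact permutation p = 0.943). Monocytes and macrophages were 4.92% ± 2.06 and 4.30% ± 4.98 (exact permutation p = 0.771, n = 4 and 4). Dendritic cells were 0.590% ± 0.371 at day 2 and 0.0818% ± 0.118 at day 10, with an exact permutation p of 0.0286 and an adjusted p of 0.2 over 7 classes. T cells were 0.232% ± 0.0979 and 1.73% ± 2.05 (exact permutation p = 0.429, adjusted p = 0.943). No class passed the threshold after adjustment. With 4 against 4 mice the smallest exact permutation p is 0.0286, which dendritic cells reached with an adjusted p of 0.2. A change in 1 class alone could therefore not pass, and the lack of a call does not show that shares stayed alike. The 10 and 11 cells of day 10 mice 1 and 2 were all neutrophils, and these mice weigh as much in the means as the others. With so few cells a rare class could easily be missed, as the exact upper limits for an unseen class were 30.85% and 28.49%. Their 0% nonetheless enters the day 10 mean and SD of every rare class. The exact permutation p of 0.0286 for dendritic cells rests in part on the 0% of day 10 mice 1 and 2. If their hashing failed, the day 10 means and the tests over n = 4 and 4 mice do not hold for these 2 mice. Their cells may then be among those of the other day 10 mice. A comparison added after seeing the data left out day 10 mice 1 and 2. In it T cells were 0.232% ± 0.0979 at day 2 and 3.45% ± 0.821 at day 10, and dendritic cells 0.590% ± 0.371 and 0.164% ± 0.122 (exact permutation p = 0.133). Monocytes and macrophages were 4.92% ± 2.06 and 8.61% ± 0.437, and neutrophils 93.1% ± 2.11 and 86.6% ± 1.56 (n = 4 and 2 mice). With 4 against 2 mice the smallest exact permutation p is 0.0667, so that none of these differences can pass.

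**Figure D1:**
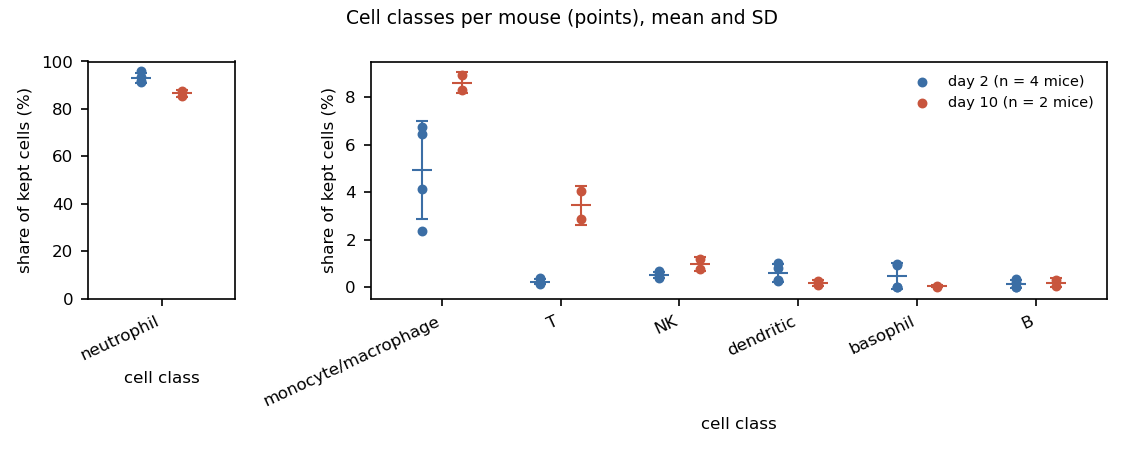
Share of each cell class among the kept cells of a mouse, in percent, with 1 point per mouse of at least 20 cells and the mean ± SD (n = 4 mice at day 2 and 2 at day 10). The day 10 mice had 87.7% and 85.5% neutrophils, and the day 2 mice 91.2% to 95.9%.

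In neutrophils the list of interferon-stimulated genes was higher at day 10, and those of specific granule and NADPH oxidase genes lower, by camera at its preset correlation. Past the threshold were 14 of 18, 4 of 10 and 3 of 7 members, and none of these 3 lists passed with an estimated correlation (adjusted p = 0.0702, 0.541 and 0.44). Of the genes that follow, Cybb is a member of the NADPH oxidase list, and Irgm1, Irf1 and Retnlg belong to none of these 3 lists. Retnlg is in the gelatinase granule list, which did not pass (camera adjusted p = 0.0744). Irgm1, an interferon-induced GTPase of defence against microbes inside cells, rose from 6.94 ± 5.72 to 115 ± 6.5 CPM (mean ± SD, n = 4 and 2 mice; log2 fold change 4.22 ± 0.40 SE, adjusted p = 6.93e-05). Irf1, a transcription factor induced by interferon, rose from 49.6 ± 33.7 to 440 ± 23.2 CPM (log2 fold change 3.44 ± 0.38, adjusted p = 0.000176). Retnlg, a resistin-like protein abundant in neutrophils, fell from 22730 ± 12170 to 2936 ± 1275 CPM (log2 fold change -2.81 ± 0.62, adjusted p = 0.00872). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, fell from 189 ± 91.8 to 28.0 ± 3.06 CPM (log2 fold change -2.51 ± 0.40, adjusted p = 0.00144). Irgm1 (ENSMUSG00000046879) lies on chromosome 11 of GRCm38 from 48861968 to 48871683. Retnlg (ENSMUSG00000022651) lies on chromosome 16 from 48872621 to 48874496 and Cybb (ENSMUSG00000015340) on chromosome X from 9435252 to 9487771.

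Among the genes open to naming by the fixed rule, the others with the largest rise were the interferon-induced GTPases Gbp5 (log2 fold change 3.97 ± 0.59), Ifi47 (3.89 ± 0.37), Gbp7 (3.71 ± 0.35) and Gbp2 (3.63 ± 0.45), and Socs1, an inhibitor of cytokine signalling (3.17 ± 0.26). With them rose Tnfaip2, a gene induced by tumour necrosis factor (3.01 ± 0.29), Mat2b, a subunit of methionine adenosyltransferase (3.00 ± 0.25), and Lars2, the mitochondrial leucyl-tRNA synthetase (3.42 ± 0.25). The largest fall among them was in Chil3, a chitinase-like secreted protein, from 321 ± 259 to 0.807 ± 0.701 CPM (log2 fold change -8.29 ± 1.75, adjusted p = 0.0257, n = 4 and 2). At day 2 its level in monocytes and macrophages was 1372% of that in neutrophils. Summed monocyte and macrophage markers stood at 656 ± 117 CPM in day 2 neutrophils and 6936 ± 1711 in those cells. Whether the day 2 level of Chil3 in neutrophils came from RNA of those cells was not tested. Cd38, an enzyme that consumes NAD, fell by 4.49 ± 0.76 on the log2 scale, and Adora2b, an adenosine receptor, fell by 3.16 ± 0.50. Mmp8, the neutrophil collagenase, fell by 2.94 ± 0.63 and Ccl9, a chemokine, fell by 2.42 ± 0.46. The rest of the 10 largest falls were in Asnsd1 (-2.78 ± 0.39), the tight junction protein Cldn1 (-2.61 ± 0.42) and Dock10 (-2.41 ± 0.36). Guanylate-binding proteins are close paralogs, and reads shared among Gbp2, Gbp5 and Gbp7 were not separated here. Measures of RNA quality differed between the days as well. Malat1, a nuclear RNA, stood at 14540 ± 2147 CPM at day 2 and 32960 ± 4144 at day 10. Neat1, another, stood at 944 ± 185 and 1344 ± 105. Of 2 genes that overlap ribosomal RNA, Gm42418 stood at 1169 ± 265 and 5115 ± 421 and AY036118 at 258 ± 81.3 and 116 ± 4.95. Lars2 was counted here among these measures, and stood higher with Gm42418 in both classes. Mitochondrial RNA stood at 0.632% ± 0.122 and 0.330% ± 0.0566 of the sums (n = 4 and 2). Summed endothelial markers stood at 34.0 ± 2.70 and 169 ± 12.4 CPM, nearly all from Pecam1 (33.7 ± 2.73 and 168 ± 12.9), which was looked up after the values were seen.

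Of 7122 genes tested by edgeR in neutrophils, 839 were higher and 542 lower at day 10 (19.4% of those tested), from sums of 1071291 to 4604027 UMIs per mouse. In 2807 genes (39.4%) every mouse of 1 day lay above every mouse of the other, where chance gives 13.3%. Without day 10 mouse 3 the counts were 384 and 143, without day 10 mouse 4 they were 525 and 137, and with free RNA subtracted 390 and 131. Without day 10 mouse 3, Chil3 (-9.74), Mmp8 (-3.00) and Cd38 (-4.53) no longer passed. Without day 10 mouse 4 the same held for Chil3 (-7.65), Mmp8 (-2.84), Retnlg (-2.34) and Ccl9 (-2.07). Retnlg did not pass with Seurat's label (-3.33, adjusted p = 0.0687). Chil3 also missed the threshold without day 2 mouse 2 (-7.82), with free RNA subtracted (-12.6, adjusted p = 0.25) and with cells thinned to equal UMIs (-10.9, adjusted p = 0.111). The same held with no filter on low counts (-8.23, adjusted p = 0.107) and under the 80% hashtag rule (-5.70, adjusted p = 0.0829). Clustering on all variable genes gave 10 neutrophil clusters that differed in their days. Those marked by Stfa2 and Retnlg, by Ngp and Lcn2, and by Csf3 and Tnf held 862, 1211 and 473 cells at day 2, and 9, 28 and 8 at day 10. Those marked by Lrg1 and Isg15 and by Lrg1 and Il15 held 62 and 24 at day 2, and 635 and 518 at day 10.

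**Figure D2:**
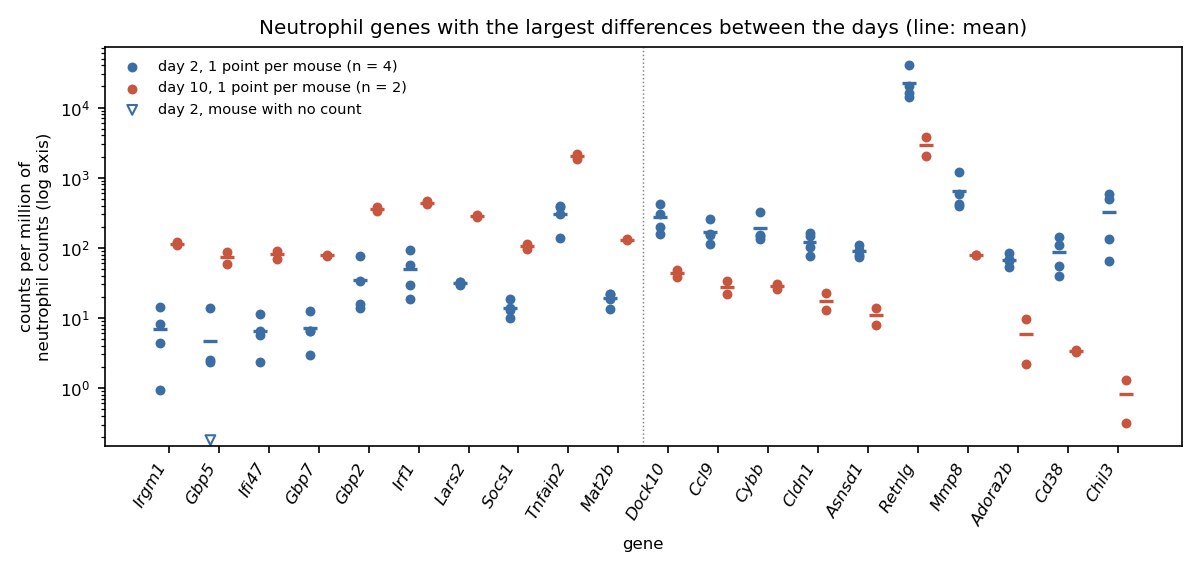
Level of the 10 genes with the largest rise and the 10 with the largest fall in neutrophils among those open to naming, in CPM on a log axis, with 1 point per mouse (n = 4 at day 2 and 2 at day 10), the mean as a line and an open triangle for a mouse with no count. Irgm1 averaged 6.94 at day 2 and 115 at day 10, and Retnlg 22730 and 2936.

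Among the 27 gene lists, interferon-stimulated genes had the smallest camera p in neutrophils, and 14 of 18 members rose and none fell (14 adjusted over the list alone; median log2 fold change 1.83). Isg15, a ubiquitin-like protein, rose from 169 ± 36.4 to 1044 ± 383 CPM (log2 fold change 2.84 ± 0.26, adjusted p = 6.05e-05, n = 4 and 2), and Isg20, an exonuclease, rose by 1.99 ± 0.22. Ifitm3, a membrane protein that restricts viral entry, was the most abundant member that did not pass (-0.51 ± 0.35, adjusted p = 0.334). The list passed camera with an adjusted p of 2.08e-09, and had an adjusted p = 0.0702 with an estimated correlation. Genes of MHC class I presentation rose in 8 of 11 members (8 adjusted over the list alone; median 1.65; camera adjusted p = 3.40e-06, and adjusted p = 0.44 with an estimated correlation). They included the light chain B2m (1.42 ± 0.22), the heavy chain H2-D1 (1.00 ± 0.25) and the immunoproteasome subunit Psmb8 (1.68 ± 0.31), while H2-K1 was at 0.22 ± 0.25 (adjusted p = 0.56). H2-D1 no longer passed without day 10 mouse 3 (0.92) or day 10 mouse 4 (1.12), under the 80% hashtag rule (0.85, adjusted p = 0.0692), with free RNA subtracted (0.99, adjusted p = 0.0559) or with Seurat's label (0.82, adjusted p = 0.0638).

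MHC class II genes, which present antigen to CD4 T cells, rose in 3 of 4 members tested (3 adjusted over the list alone; median 2.11; camera adjusted p = 0.00165, and adjusted p = 0.44 with an estimated correlation). H2-Aa rose from 3.20 ± 2.40 to 24.3 ± 6.67 CPM (log2 fold change 3.25 ± 0.40, n = 4 and 2), and H2-Eb1 rose by 2.93 ± 0.30. Cd74, the invariant chain, rose by 1.30 ± 0.29, while H2-Ab1 stood at 0.64 ± 0.42 (adjusted p = 0.315). Cd74 did not pass without day 10 mouse 3 (1.23). At these low levels free RNA, at its upper share of 6.09% of day 10 neutrophil counts, amounted to 97.4% of the counts of H2-Aa, 62.9% of H2-Eb1 and 81.0% of Cd74. The homing and ageing receptors rose in 5 of 9 members (5 higher and 1 lower adjusted over the list alone; median 1.37; camera adjusted p = 0.00431, and adjusted p = 0.541 with an estimated correlation). Examples were the chemokine receptor Cxcr2 (1.41 ± 0.29) and the granulocyte colony-stimulating factor receptor Csf3r (1.37 ± 0.26). Without day 10 mouse 3 these stood at 1.09 and 1.18 and did not pass. Heat shock and immediate early genes, which tissue digestion can induce, rose in 5 of 13 members (5 adjusted over the list alone; median 0.67; camera adjusted p = 0.0183, and adjusted p = 0.679 with an estimated correlation), with Fos at 2.58 ± 0.26, Egr1 at 2.04 ± 0.28 and Dusp1 at 1.96 ± 0.25. The call of this list was lost without day 10 mouse 4 (adjusted p = 0.308) and without day 2 mouse 1 (adjusted p = 0.0505).

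In the other direction, specific granule genes fell in 4 of 10 members and none rose (4 adjusted over the list alone; median -1.82; camera adjusted p = 0.00159, and adjusted p = 0.541 with an estimated correlation). Lcn2, which binds bacterial siderophores, fell from 19100 ± 3906 to 3799 ± 935 CPM (log2 fold change -2.15 ± 0.37, adjusted p = 0.00201, n = 4 and 2), and did not pass without day 10 mouse 3 (-1.98). Camp, an antimicrobial peptide precursor, fell by 3.19 ± 0.49 but stood at 0.83 under the rule that asks the first hashtag for 80% of the hashtag counts. Wfdc21 did not pass (-0.83 ± 0.35, adjusted p = 0.111). NADPH oxidase genes fell in 3 of 7 members (5 adjusted over the list alone; median -1.03; camera adjusted p = 0.00333, and adjusted p = 0.44 with an estimated correlation), among them the cytosolic subunit Ncf1 (-1.34 ± 0.24) and the GTPase Rac2 (-1.22 ± 0.24). Rac2 did not pass without day 10 mouse 3 (-1.25) or day 10 mouse 4 (-1.17). Glycolysis genes fell in 6 of 16 members (6 adjusted over the list alone; median -0.60; camera adjusted p = 0.00333, and adjusted p = 0.679 with an estimated correlation), with Gapdh at -0.96 ± 0.30 and Pgam1 at -0.94 ± 0.27. This list did not pass with hashtag number as a block (adjusted p = 0.0774). Neither gene passed without day 10 mouse 3 (-0.90 and -0.73), day 10 mouse 4 (-1.0 and -1.16) or day 2 mouse 1 (-1.06 and -0.98). Gapdh also did not pass without day 2 mouse 4 (-1.0). Neither passed with hashtag number as a block (-0.77 and -0.76, adjusted p = 0.115 and 0.0802) or with free RNA subtracted (-1.06 and -1.03, adjusted p = 0.0751 and 0.0664).

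Translation genes, which are ribosomal proteins and elongation factors, had 1 member of 13 that fell, Eef1a1 (-0.97 ± 0.26; 1 adjusted over the list alone; list median -0.51). That list passed camera (adjusted p = 0.00313, and adjusted p = 0.581 with an estimated correlation), but not without day 10 mouse 3 (adjusted p = 0.0725) or with free RNA subtracted (adjusted p = 0.105). Eef1a1 stood at -0.88 without day 10 mouse 3, -1.02 without day 10 mouse 4 and -1.08 with free RNA subtracted (adjusted p = 0.0508), none of which passed. The share of RNA from mitochondrial genes, lower at day 10, moved with it.

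The other 18 lists did not pass in neutrophils. Inflammatory cytokines and chemokines had 4 of 15 members that rose and 1 that fell (5 and 2 adjusted over the list alone). Il1b, the precursor of interleukin-1 beta, rose from 3646 ± 869 to 13270 ± 636 CPM (log2 fold change 2.06 ± 0.31, adjusted p = 0.000826, n = 4 and 2), and Osm, the cytokine oncostatin M, rose by 1.75 ± 0.35 but did not pass with Seurat's label (1.40, adjusted p = 0.063). The most abundant member, the neutrophil chemoattractant Cxcl2, did not pass (0.96 ± 0.39, adjusted p = 0.105). Nlrp3, a sensor that assembles an inflammasome, rose by 1.47 ± 0.30 among 3 risen and 1 fallen of 13 bacterial sensing genes (4 and 1 adjusted over the list alone), though not past the threshold without day 10 mouse 3 (1.35). Areg, a ligand of the epidermal growth factor receptor, rose by 3.69 ± 0.45 among 3 risen and 2 fallen of 13 matrix and angiogenesis genes (4 and 2 adjusted over the list alone). Its day 10 level rests on 316 UMIs in 42 of 2530 neutrophils (1.66%), where 38 of 98 day 10 T cells had a UMI. Whether these 42 barcodes were doublets with other cells was not tested. Alarmins and S100 proteins had no member past the threshold among 7, with S100a9 at 0.29 ± 0.39 (adjusted p = 0.648), and azurophil granule genes none among 3 (0 higher and 2 lower adjusted over the list alone). Gelatinase granule genes fell in 3 of 8, hypoxia genes in 2 of 12 and immune regulation genes in 2 of 11, with the same counts adjusted over the list alone. Of the rest, NF-kappaB feedback had 2 higher and 2 lower of 13, iron and haem 2 and 2 of 10, extracellular trap 2 and 1 of 5, and efferocytosis 2 and 1 of 6. Eicosanoid synthesis had 1 and 1 of 7, unfolded protein response 1 and 0 of 11 and proliferation 1 and 0 of 3, all unchanged adjusted over the list alone. Phagocytic receptors had 1 and 1 of 9, apoptosis 1 and 1 of 15 and oxidative phosphorylation 1 and 0 of 17, which became 2 and 1, 1 and 2, and 0 and 0 adjusted over the list alone. Median, mean and test differed in sign for the NF-kappaB, extracellular trap, eicosanoid, immune regulation and oxidative phosphorylation lists.

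**Figure D3:**
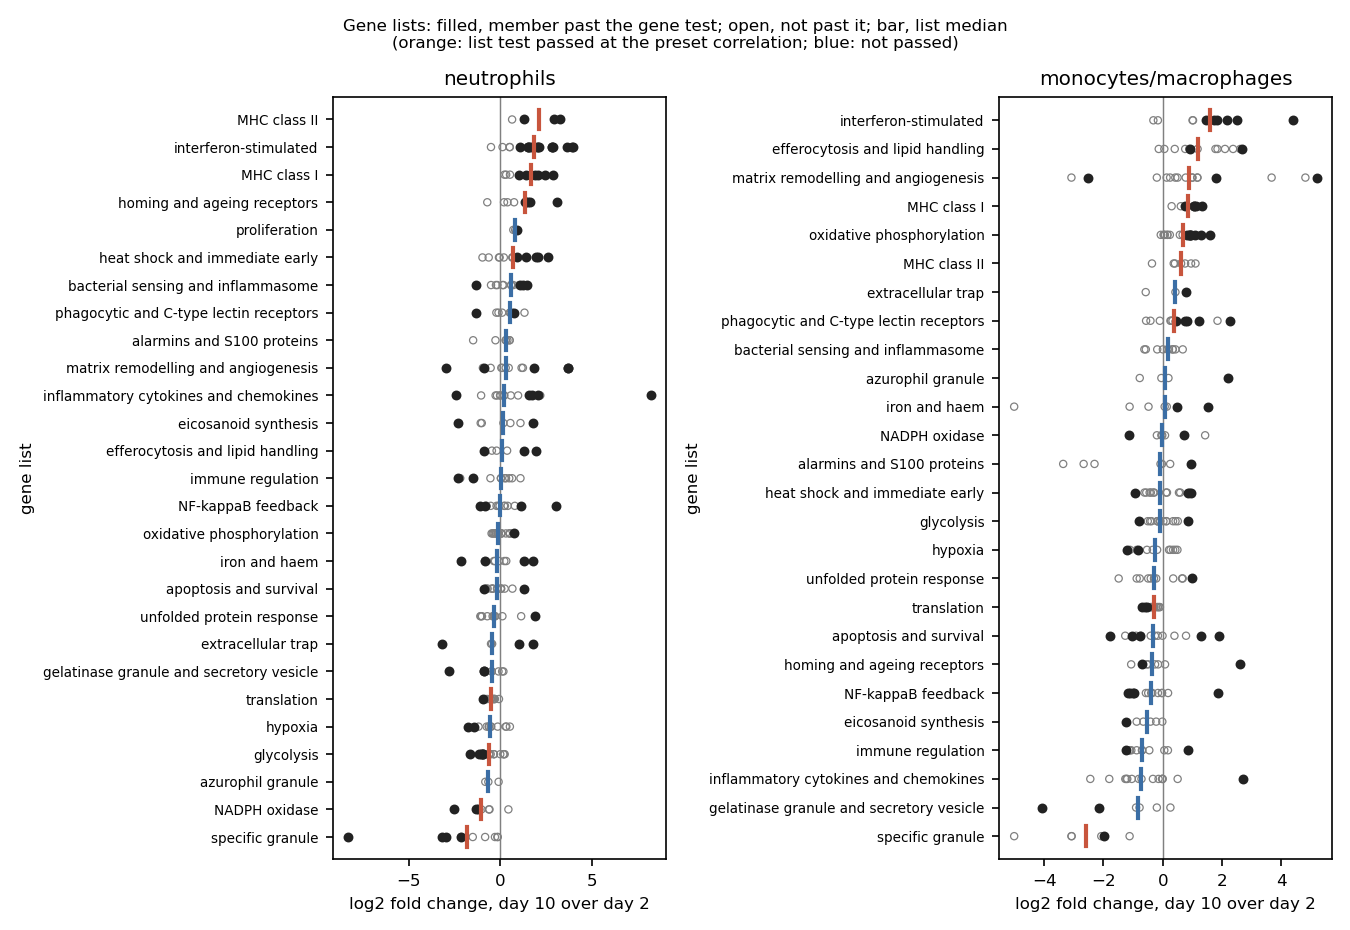
Log2 fold change, day 10 minus day 2, of each member of the gene lists in neutrophils (n = 4 and 2 mice) and in monocytes and macrophages (n = 3 and 2 mice). Filled points passed the gene test, and an orange bar marks lists that passed camera at the preset correlation. The interferon-stimulated members had a median of 1.83 in neutrophils and 1.61 in monocytes and macrophages.

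Neutrophils were also sorted into 4 states by genes not past the threshold between the days, to ask whether their composition shifted. Genes past the threshold were left out, so that a shift carried by those genes alone could not show as a state. A state marked by the hypoxia-related genes Ero1l, Bnip3 and Ldha and by Il1a made up 42.9% ± 20.2 of neutrophils at day 2 and 18.3% ± 9.56 at day 10 (n = 4 and 4 mice; exact permutation p = 0.0857). Ero1l itself stood at 1228 ± 397 and 488 ± 262 CPM (log2 fold change -1.19 ± 0.41, adjusted p = 0.0631, n = 4 and 2). A state marked by Ifitm1, Anxa1 and the matrix protein Tgfbi made up 23.0% ± 9.23 and 40.6% ± 21.6 (exact permutation p = 0.229, n = 4 and 4). The day 10 means include the mice with 10 and 11 cells. Over mice with at least 20 cells this state made up 23.0% and 53.5% (exact permutation p = 0.0667, the smallest possible with n = 4 and 2). Without day 10 mouse 1 its difference was 27.9 points (exact permutation p = 0.0286, adjusted p = 0.114), and without day 10 mouse 3 the state made up 34.0% of day 10 neutrophils. The state marked by Creg1, Psap and Tnf made up 18.1% ± 11.6 and 28.1% ± 12.4, and that marked by Emp3, Gpx1 and Lyz2 16.0% ± 12.3 and 13% ± 5.29 (exact permutation p = 0.314 and 0.743). None passed the threshold after adjustment. The smallest exact permutation p with n = 4 and 4 is 0.0286, which for a lone state of 4 gives an adjusted p of 0.114. A shift in 1 state alone could therefore not pass. States formed anew from cells with at least 1000 UMIs, not matched to these, included 1 of 43.3% at day 2 and 20.2% at day 10 and 1 of 12.2% and 34.9% (means, n = 4 and 4; exact permutation p = 0.0286, adjusted p = 0.0571 for each).

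In monocytes and macrophages the lists of interferon-stimulated, MHC class I and oxidative phosphorylation genes were higher at day 10, and those of translation and specific granule genes lower, by camera at its preset correlation. Past the threshold were 6 of 10, 5 of 9, 8 of 17, 3 of 13 and 1 of 6 members, and none of these 5 lists passed with an estimated correlation (adjusted p = 0.417, 0.473, 0.397, 0.397 and 0.417). Cxcl10, a chemokine that attracts T cells, rose from 5.71 ± 6.72 to 84.8 ± 33.8 CPM (mean ± SD, n = 3 and 2 mice; log2 fold change 4.41 ± 0.61, adjusted p = 0.00335). Bcl2a1a, an inhibitor of apoptosis with near-identical paralogs, rose by 3.72 ± 0.38. Ly6i rose by 3.33 ± 0.47, Ly6a by 3.27 ± 0.49 and Anpep, an aminopeptidase, by 2.70 ± 0.40. Lrg1, a secreted leucine-rich glycoprotein, fell from 256 ± 54.5 to 36.1 ± 20.5 CPM (log2 fold change -2.77 ± 0.36, adjusted p = 0.00335, n = 3 and 2), and Pfkfb3, a regulator of glycolysis, fell by 2.13 ± 0.24. Cxcl10 (ENSMUSG00000034855) lies on chromosome 5 from 92346638 to 92348889, and Lrg1 (ENSMUSG00000037095) on chromosome 17 from 56119678 to 56122001.

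Others with a large rise were Lars2 (3.84 ± 0.29), Stfa3, a stefin with close paralogs (3.66 ± 0.59), Rbis (2.98 ± 0.32), the complement factor Cfb (2.92 ± 0.56) and Dst, a cytoskeletal linker (2.72 ± 0.50). Others with a large fall were Retnlg (-4.07 ± 0.30), Thbs1, or thrombospondin-1 (-2.51 ± 0.51), Adgrl2 (-2.44 ± 0.65), Leng8 (-2.28 ± 0.34), Itpkb (-2.26 ± 0.38), Klhl2 (-2.22 ± 0.29), Stx11 (-2.17 ± 0.47) and the formyl peptide receptor Fpr1 (-2.14 ± 0.42). The summed neutrophil markers stood at 14930 ± 13140 CPM in the same sums at day 2 and 2200 ± 463 at day 10, and Gm42418 stood at 2172 ± 908 and 15430 ± 5531 (n = 3 and 2). Other measures of RNA quality stood lower at day 10, with Neat1 at 1168 ± 137 and 327 ± 49.6 CPM, Malat1 at 12000 ± 314 and 9804 ± 1984, and AY036118 at 389 ± 184 and 245 ± 5.45. Mitochondrial RNA stood at 3.03% ± 0.446 and 1.78% ± 0.148 of these sums, median UMIs per cell at 4562 ± 543 and 8500 ± 1022, and summed endothelial markers at 30.3 ± 7.33 and 93.5 ± 8.24 CPM. Calls lost without day 10 mouse 3 were Cfb (2.50), Stfa3 (3.53), Thbs1 (-2.08), Adgrl2 (-2.27), Stx11 (-2.24) and Fpr1 (-1.91). Calls lost without day 10 mouse 4 were Stfa3 (3.85), Thbs1 (-3.02), Adgrl2 (-2.56), Stx11 (-2.10) and Fpr1 (-2.38). Without day 2 mouse 3 those lost were Cfb (2.69), Dst (2.71), Ly6a (3.04), Adgrl2 (-2.23), Itpkb (-2.16) and Stx11 (-2.39). Thbs1 was also lost without day 2 mouse 1 (-2.58) or day 2 mouse 2 (-2.15). With cells thinned to equal UMIs, Pfkfb3 (-1.49, adjusted p = 0.15) and Lrg1 (-2.74, adjusted p = 0.0605) did not pass, nor did Retnlg (-3.57, adjusted p = 0.0513) and Adgrl2 (-2.22, adjusted p = 0.0638) under the 80% hashtag rule or Stfa3 with DESeq2 (4.17, adjusted p = 0.223). Thbs1 missed the threshold in 5 other settings, with adjusted p of 0.0503 to 0.0548.

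The test of monocytes and macrophages was added after seeing the data, since the planned minimum of 3 mice per day was not met, and used sums of 152480 to 1186871 UMIs. Of 5282 genes tested by edgeR, 364 were higher and 366 lower at day 10 (13.8%), and in 2393 (45.3%) every mouse of 1 day lay above every mouse of the other, where chance gives 20%. The counts were 116 and 64 without day 10 mouse 3, 78 and 56 without day 10 mouse 4, 180 and 156 without day 2 mouse 1, 62 and 72 without day 2 mouse 3, and 175 and 167 with DESeq2. The class differed in its clusters between the days. Clusters marked by Chil3 and Vcan and by Saa3 and Adgrl2 held 74 and 74 cells at day 2, and 3 and 5 at day 10. A cluster marked by Mmp12 and Cd36 held 36 and 118, and those marked by C1qa with Ms4a7 and by C1qa with Folr2 held 1 and 4 at day 2, and 30 and 25 at day 10. The gene test sums over all of these.

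Oxidative phosphorylation genes rose in 8 of 17 members in monocytes and macrophages (10 adjusted over the list alone; median 0.67; camera adjusted p = 1.11e-05, and adjusted p = 0.397 with an estimated correlation). Among them were the cytochrome oxidase subunits Cox5b (1.09 ± 0.20) and Cox6c (0.89 ± 0.14), which did not pass without day 10 mouse 4 (1.06 and 0.87), nor Cox5b without day 2 mouse 3 (0.95) or with thinned cells (0.69, adjusted p = 0.2). MHC class I genes rose in 5 of 9 (6 adjusted over the list alone; median 0.84; camera adjusted p = 0.00014, and adjusted p = 0.473 with an estimated correlation), with H2-D1 at 1.05 ± 0.16 and B2m at 1.14 ± 0.18, the latter not past the threshold without day 10 mouse 4 (0.97). Interferon-stimulated genes rose in 6 of 10 (6 adjusted over the list alone; median 1.61; camera adjusted p = 0.00222, and adjusted p = 0.417 with an estimated correlation). Isg15 rose by 1.83 ± 0.36 and did not pass without day 10 mouse 3 (1.59) or day 2 mouse 3 (1.33). Efferocytosis and lipid handling genes rose in 2 of 13 (8 adjusted over the list alone; median 1.18; camera adjusted p = 0.000317, and adjusted p = 0.397 with an estimated correlation). These were Trem2, a lipid-sensing receptor (0.92 ± 0.25), and Fabp5, a fatty acid carrier (2.66 ± 0.49). Neither passed without day 10 mouse 3 (0.82 and 2.56), day 10 mouse 4 (1.06 and 2.82) or day 2 mouse 3 (0.85 and 2.54), nor with thinned cells (0.31 and 1.43, adjusted p = 0.813 and 0.414). Trem2 also did not pass with DESeq2 (adjusted p = 0.0817). Fabp5 did not pass with at least 250 or 1000 UMIs (adjusted p = 0.079 and 0.056), with the 5% mitochondrial limit (adjusted p = 0.0651), without high Scrublet scores (adjusted p = 0.0692) or with the mouse of 19 cells (adjusted p = 0.052).

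Phagocytic and C-type lectin receptors rose in 5 of 12 members of this class (6 higher and 1 lower adjusted over the list alone; median 0.39; camera adjusted p = 0.00222, and adjusted p = 0.397 with an estimated correlation), among them the inhibitory Fc receptor Fcgr2b (1.24 ± 0.16), which did not pass with thinned cells (0.66, adjusted p = 0.248). Matrix remodelling genes had 2 higher and 1 lower of 16 (3 and 1 adjusted over the list alone; median 0.88; camera adjusted p = 0.0277, and adjusted p = 0.397 with an estimated correlation), with Timp2, an inhibitor of metalloproteinases, at 1.81 ± 0.25. No member of 7 passed among MHC class II genes (0 adjusted over the list alone; median 0.62; camera adjusted p = 0.0418, and adjusted p = 0.536 with an estimated correlation). Cd74 stood at 0.96 ± 0.45 (adjusted p = 0.239). The list did not pass without day 10 mouse 3 (adjusted p = 0.064) or day 10 mouse 4 (adjusted p = 0.0559). Specific granule genes had 1 of 6 that fell, the peptidoglycan-binding Pglyrp1 (-1.98 ± 0.47; 1 adjusted over the list alone; median -2.57; camera adjusted p = 0.000877, and adjusted p = 0.417 with an estimated correlation). Pglyrp1 stood at -1.37 without day 10 mouse 3, -2.07 without day 2 mouse 1 and -2.18 without day 2 mouse 3 and passed in none of these. Lcn2 stood at -5.01 ± 1.6 and did not pass (adjusted p = 0.151), and the summed neutrophil markers stood lower with this list. Translation genes fell in 3 of 13 (3 adjusted over the list alone; median -0.30; camera adjusted p = 0.000583, and adjusted p = 0.397 with an estimated correlation), with Rpsa at -0.69 ± 0.13, which did not pass without day 10 mouse 3 (-0.63), day 10 mouse 4 (-0.69) or day 2 mouse 3 (-0.72).

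The remaining lists did not pass in monocytes and macrophages. Among azurophil granule genes 1 of 4 rose, Cd63, a lysosomal membrane protein (2.22 ± 0.25), and among homing receptors Itgax, the integrin CD11c, rose by 2.59 ± 0.34 and 1 other of 8 fell. Arg1, which breaks down arginine, rose by 0.86 ± 0.19 among 1 higher and 1 lower of 11 immune regulation genes (1 and 4 adjusted over the list alone), but not past the threshold without day 10 mouse 3 (0.83), day 10 mouse 4 (0.94) or day 2 mouse 3 (0.83), or with thinned cells (0.60, adjusted p = 0.19). NF-kappaB feedback had 1 higher and 4 lower of 13, gelatinase granule 0 and 2 of 6, iron and haem 2 and 0 of 7, extracellular trap 1 and 0 of 3 and eicosanoid synthesis 0 and 1 of 6. Bacterial sensing had none of 10, and proliferation none of 2 and too few members for camera. In these, and in the azurophil granule and homing lists, the counts adjusted over the list alone were the same. They differed for alarmins (1 and 0 of 7, then 1 and 1), inflammatory cytokines (1 and 0 of 15, then 0 and 0), NADPH oxidase (1 and 1 of 7, then 2 and 1) and glycolysis (1 and 1 of 16, then 2 and 1). They also differed for hypoxia (0 and 2 of 12, then 0 and 3), unfolded protein response (1 and 0 of 11, then 2 and 2), heat shock (2 and 1 of 14, then 4 and 1) and apoptosis (2 and 3 of 14, then 2 and 4). Median, mean and test differed in sign for NADPH oxidase, glycolysis, iron and haem, and heat shock.

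Whether both classes changed alike was asked by testing the difference between their day effects. Il1b rose in neutrophils and stood at -0.00 in monocytes and macrophages, a difference of -2.17 ± 0.28 on the log2 scale (monocytes and macrophages minus neutrophils; adjusted p = 3.25e-05, n = 3 and 2 mice with both classes). Lrg1 had the smallest p of this test, with a difference of -4.84 ± 0.34 (adjusted p = 2.41e-09), a rise of 2.19 in neutrophils and a fall in monocytes and macrophages. Cybb, which fell in neutrophils, differed by 2.08 ± 0.30, Fcgr2b by 2.28 ± 0.38 and Cd63 by 2.33 ± 0.32. Fos (-2.10 ± 0.27), Egr1 (-2.17 ± 0.33), Osm (-2.16 ± 0.29) and H2-Aa (-3.06 ± 0.38) had the higher day effect in neutrophils. For neutrophil genes such a difference can come from neutrophil RNA in the monocyte and macrophage sums, where summed neutrophil markers stood at 14930 ± 13140 CPM at day 2 and 2200 ± 463 at day 10. H2-Aa is not such a gene, and free RNA at its upper share would supply 97.4% of its day 10 counts in neutrophils. No difference passed for B2m (-0.31 ± 0.26, adjusted p = 0.517), H2-D1 (0.14 ± 0.27, adjusted p = 0.805), Isg15 (-1.05 ± 0.39, adjusted p = 0.0877) or Gbp2 (-1.45 ± 0.58, adjusted p = 0.125). It did pass for other interferon-related genes, among them Isg20 (-2.49) and Gbp7 (-2.28). Of 7717 genes tested by edgeR, 267 had the higher day effect in monocytes and macrophages and 521 in neutrophils. These counts were 104 and 199 without day 10 mouse 3, 176 and 405 without day 10 mouse 4, 96 and 250 without day 2 mouse 3, and 117 and 246 with free RNA subtracted. Of 4778 genes tested in both classes, 70 were higher at day 10 in both, where independence gives 32.5. In both classes 82 were lower, where it gives 29.0, and 40 went opposite ways. The classes share mice and libraries.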

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

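Tests chosen only after the result was seen were those of monocyte or macrophage RNA in neutrophils, of neutrophil RNA in monocytes and macrophages, of clusters of neutrophils, and of the splits of the mice. So was the test of monocytes and macrophages itself.

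Interferon-stimulated genes were higher at day 10 in neutrophils, in 14 of 18 members, although the list had an adjusted p = 0.0702 with an estimated correlation. At its upper share, free RNA of the day 10 library would supply 4.62% of the day 10 counts of these members (median, with a range of 2.24% to 9.29%), which argues against free RNA as their source. Their level in neutrophils was 373% of that in monocytes and macrophages (median, 82.6% to 2276%), which argues against RNA of those cells in neutrophil droplets. A shift among neutrophil states stays open. The 4 states, with a median log2 difference of 1.74 to 3.39 between the days within each, were formed without the called genes. The bound set for them beforehand was therefore wrong. Within clusters formed with all variable genes the difference was 2.22, 2.74 and 3.16 in 3 but 1.00 and -0.29 in 2. The 2.74 rests on 1 day 2 mouse and the -0.29 on 1 day 10 mouse. These clusters could be formed by the tested genes themselves, which shrinks differences within them, so that they cannot decide the question either. A change of neutrophils with the phase of infection may account for the rise and stays a hypothesis, untested apart from library preparation, since day and library cannot be told apart.

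MHC class II genes were higher at day 10 in neutrophils, in 3 of 4 members, although the list had a camera adjusted p = 0.44 with an estimated correlation. For H2-Aa, H2-Eb1 and Cd74, free RNA at its upper share would supply 81.0% of the day 10 counts (median, 62.9% to 97.4%), so that free RNA could be their source, although the list still passed with free RNA subtracted (adjusted p = 0.0421). The upper share overstates free RNA at day 2, where it would give 19.8, 31.4 and 53.5 CPM against 2.99, 5.26 and 22.7 counted. Carry-over of monocyte or macrophage RNA stays open too, since the median level over that in monocytes and macrophages was 4.71 times that of C1qa, C1qb, C1qc and Apoe, but Apoe (1.5%) lay among H2-Aa (1.24%), H2-Eb1 (2.11%) and Cd74 (0.973%), an overlap that was made part of the criterion after the value was seen. Expression by day 10 neutrophils stays open beside both and was not tested.

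Specific granule genes passed as lower at day 10 in monocytes and macrophages at the preset correlation alone (adjusted p = 0.417 with an estimated one), with 1 of 6 members past the threshold (Pglyrp1), and the summed neutrophil markers also stood lower there. If neutrophil RNA in their droplets were the whole cause, members and neutrophil markers would reach like shares of their neutrophil level at day 2. The median of the 6 members, 40.7%, was 7.39 times that of Retnlg, Mmp9 and G0s2 (5.51%). Members ranged from 10.3% for Pglyrp1 and 17.1% for Lcn2 to 99.1% for Hp and 1372% for Chil3. This argues against neutrophil RNA as the whole cause for Hp and Chil3. It cannot decide for the list, since the ratio depends on the markers taken. S100a8, a neutrophil marker not among these 3, stood at 9505 CPM in monocytes and macrophages at day 2, and at 60030 in all day 2 barcodes with 1 hashtag. For Pglyrp1, the member past the threshold, and for Lcn2 a part from neutrophils may remain. A change of the cells present or of their expression with the phase of infection stays open, and was not tested apart from the library.

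In neutrophils, the real split of the 6 mice into 4 and 2 gave 1381 genes and was the only one of 15 splits with as many (1), where the highest other split gave 0. With 15 splits a share under 0.05 cannot be reached. Every other split also puts mice of both days into 1 group, where any day difference widens the spread. Few or no genes could pass in them, so that the splits do not bear on chance.

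In 12 of 132 groups of 4 mice (9.09%) the highest or lowest mouse stood far from the others, where chance gives about 1 in 20. Day 2 mouse 4 stood apart in neutrophils for Nfkbia (5363 CPM against 3015 to 3358), Zfp36 (637 against 365 to 400), Cflar (713 against 449 to 473), Cybb (327 against 134 to 151), Hspa5 (619 against 158 to 174) and H2-Ab1 (37.1 against 14.3 to 15.9). Day 2 mouse 2 stood apart for Alox5ap (2843 CPM against 1358 to 1512), Steap4 (28 against 48.3 to 51.1), H2-Eb1 (1.87 against 5.51 to 6.0) and median UMIs per neutrophil (2278 against 1450 to 1545). Psmb8 in day 2 mouse 3 was at 66.1 CPM against 23.1 to 29.99 in the others. The basophil share of day 10 mouse 3 was 0.0624% (1 cell) against 0% in the others.

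Of 155 named genes, 66 differed between the classes in their day effect by the interaction test, 28 with the higher effect in monocytes and macrophages and 38 in neutrophils. The log2 differences, monocytes and macrophages minus neutrophils, were Stfa3 5.34, Chil3 4.47, Cfb 4.46, Hbegf 3.91, Bcl2a1a 2.73, Cd38 2.69, Ly6i 2.57, Asnsd1 2.53, Cd63 2.33, Fcgr2b 2.28, Itgax 2.15, Cybb 2.08, Blvrb 1.99 and Timp2 1.84. Smaller ones of this direction were Adora2b 1.72, Higd1a 1.61, Fabp5 1.55, Cyba 1.37, Ccl9 1.35, Lgals3 1.33, Ncf1 1.29, Cox6c 1.27, Clec4n 1.12, Dock10 1.10, Tpi1 1.06, Pgam1 1.05, Bcl2a1b 0.92 and Ctsd 0.90. Among those with the higher effect in neutrophils were Lrg1 -4.84, Cxcr2 -3.16, S100a9 -3.10, H2-Aa -3.06, H2-Eb1 -2.73, Mat2b -2.67, Isg20 -2.49, Itpkb -2.45, Stx11 -2.44, Lmnb1 -2.43, Dusp1 -2.40, Gbp7 -2.28, Egr1 -2.17, Il1b -2.17, Osm -2.16, Thbs1 -2.11 and Fos -2.10. Smaller ones were Klhl2 -1.89, Csf3r -1.76, Pglyrp1 -1.76, Leng8 -1.70, Nlrp3 -1.62, Pfkfb3 -1.42, Ier3 -1.36, Fpr1 -1.34, Clec4e -1.33, Nfkbiz -1.28, Wfdc21 -1.24, Hspa5 -1.21, Zfp36 -1.21, Tnfaip2 -1.17, Cflar -1.12, Junb -1.12, Cd44 -1.04, Mxi1 -1.02, Atf3 -1.02 and Jun -1.01. S100a9 did not pass in neutrophils (0.29, adjusted p = 0.648), and for it and other neutrophil genes such as Cxcr2 the difference may come from the monocyte and macrophage sums, where summed neutrophil markers stood at 14930 CPM at day 2 and 2200 at day 10. Hbegf rests on very few counts in monocytes and macrophages at day 2 (0.667 ± 1.16 CPM, n = 3).

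In data that no comparison used, day 10 hashtags 1 and 2 had a median of 9 counts each in cells of the other mice, where hashtags 3 and 4 had 1. Day 10 barcodes with no hashtag had Isg15 at 795 CPM, near the 761 of barcodes with 1 hashtag.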

How the results depend on the processing

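Alternatives added after seeing the data were Seurat's own mouse label, leaving out the 10% of cells with the highest Scrublet score, the mouse of 19 cells, and shares over mice with at least 20 cells. Hashtag number as a block could not be fitted for monocytes and macrophages, where no residual degrees of freedom remained, and was not run. Over all alternatives, values of named genes kept direction and side of the threshold 1766 times in neutrophils (169 weaker, 17 stronger, 24 reversed) and 1466 times in monocytes and macrophages (208 weaker, 19 stronger, 39 reversed). Lists past camera kept theirs 67 times in neutrophils (14 weaker) and 52 times in monocytes and macrophages (11 weaker), with no reversal. With an estimated correlation 0 of 9 lists passed in neutrophils and 0 of 9 in monocytes and macrophages. Depth sets how many genes can be tested, as thinning to 500 UMIs left 1041 of 5282 genes in monocytes and macrophages. Leaving out a mouse tests with fewer samples, although more genes passed without day 2 mouse 2 in both classes. For the other changes the cause was not tested. Of the genes named by the rule whose sign turned, Camp in neutrophils was the one that had passed as reported (-3.19).

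Gene counts, given as higher and lower at day 10, were 496 and 279 in neutrophils under the 80% hashtag rule, 390 and 131 with free RNA subtracted, and 439 and 256 with thinned cells. In monocytes and macrophages they were 51 and 41 with thinned cells, 175 and 167 with DESeq2, and 635 higher with no filter. Of the neutrophil genes, 474 and 238 under the hashtag rule, 388 and 131 with free RNA subtracted and 415 and 209 with thinned cells were among those reported. With free RNA subtracted 1 gene was called the opposite way, mt-Co3, named after its values were seen. The interaction gave 117 and 246 with free RNA subtracted. Leaving out 1 mouse gave neutrophil counts of 384 to 926 higher and 137 to 643 lower, monocyte and macrophage counts of 62 to 523 and 56 to 527, and interaction counts of 96 to 274 and 199 to 507.

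Differences in share (percentage points, day 10 minus day 2) for neutrophils were -16.6 under the hashtag rule, -6.53 over mice with at least 20 cells, -0.149 with a 5% mitochondrial limit, -3.28 with Seurat's label and -0.218 with the highest Scrublet scores left out. For monocytes and macrophages they were 9.15, 3.69 and 2.84 under the hashtag rule, over mice with 20 cells and with Seurat's label. For NK cells they were 3.82, 0.449, 0.0814, 0.0154 and 0.0116 under the hashtag rule, over mice with 20 cells, with the mitochondrial limit, without high Scrublet scores and with at least 250 UMIs. For B cells they were 0.0316, 0.0498 and 0.0438 under the first 3 of these. Leaving out 1 mouse gave -2.07 to 2.76 for neutrophils, -2.15 to 0.819 for monocytes and macrophages, -0.257 to 0.130 for NK cells and -0.116 to 0.0242 for B cells. Among neutrophil states, that of Creg1 and Psap stood at -0.173 over mice with 20 cells, and that of Emp3 and Gpx1 at -6.64 to 1.87 leaving out 1 mouse. For T cells the difference was 1.49 as planned, 4.12 under the hashtag rule, 3.22 over mice with 20 cells and 0.724 to 2.07 leaving out 1 mouse. For dendritic cells it was -0.508 as planned and -0.426 over mice with 20 cells. Under the hashtag rule 3, 12, 985 and 182 barcodes were called for day 10 mice 1 to 4 before the cell filters, and each mouse weighed alike. The day 10 neutrophil share was then 75.6% ± 31.4 (mean ± SD, n = 4), so that the differences under this rule rest partly on mice of few cells. With at least 1000 UMIs, 1 state differed by -23.1 points and 1 by 22.7 (adjusted p = 0.0571 each), and at state resolution 0.8 a state differed by -15.2 (exact permutation p = 0.0286, adjusted p = 0.171). No share or state test passed as reported.

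Log2 fold changes with the opposite sign in neutrophils, under the hashtag rule, were Camp 0.83 (adjusted p = 0.54), Cox8a -0.13, Slpi -0.11 and Wfdc17 -0.082. Others were Cox8a at -0.018 with free RNA subtracted, -0.014 with thinned cells, -0.032 with Seurat's label and -0.005 with at least 1000 UMIs. Wfdc17 was at -0.023 with free RNA subtracted, -0.400 with Seurat's label, -0.111 with at least 1000 UMIs and -0.020 at resolution 0.5, and Fth1 at 0.022 with hashtag number as a block. Leaving out 1 mouse gave Cox8a -0.040 to 0.116, Fth1 -0.162 to 0.024, H2-K1 -0.020 to 0.460, S100a9 -0.073 to 0.607, Slpi -0.049 to 0.230 and Wfdc17 -1.067 to 0.672.

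In monocytes and macrophages, Ctsc was at 0.083 under the hashtag rule, 0.078 with no filter, 0.060 with the mitochondrial limit, 0.068 and 0.041 with at least 250 and 1000 UMIs, and 0.059 with the mouse of 19 cells. Cybb was at 0.24 under the hashtag rule, 0.013 with thinned cells, 0.089 with no filter, 0.058 with the mitochondrial limit, 0.064 and 0.048 with at least 250 and 1000 UMIs, 0.068 with the mouse of 19 cells and 0.002 with DESeq2's size factors. Cxcl2 was at 0.13 under the hashtag rule, 0.127 with thinned cells, 0.141 with no filter, 0.032 without high Scrublet scores, 0.002 at resolution 0.5 and 0.007 with Scrublet calls kept. Gapdh was at 0.04 under the hashtag rule and 0.026 with no filter, Cox4i1 at 0.145 with thinned cells and 0.046 with no filter, Fth1 at -0.014 with thinned cells and -0.003 with the mitochondrial limit, and Lmnb1 at 0.391 with thinned cells. Leaving out 1 mouse gave Ctsc -0.197 to 0.268, Cxcl2 -0.540 to 0.915, Cybb -0.095 to 0.095, Fth1 -0.163 to 0.422, Gapdh -0.248 to 0.117 and Slpi -2.523 to 0.061.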

Other observations

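All tests between the days in neutrophils of the single genes named in this part were looked up after their values were seen. The T cells of day 10, 98 cells from 2 mice, carried RNA of type 17 cytokines. Il17a, which drives neutrophil recruitment by epithelial and stromal cells, had a UMI in 65 of 98 T cells (66.3%, exact 95% interval 56.1% to 75.6%) and in 32 of 2530 day 10 neutrophils (1.27%), with median depths of 5779 and 2941 UMIs. Il17f had a UMI in 36 of 98 T cells (36.7%) and in 6 of 2530 neutrophils (0.237%). The granulocyte and macrophage growth factor Csf2 was seen in 26 of 98 T cells (26.5%), Areg in 38 (38.8%) and Il22, a cytokine that acts on epithelium, in 12 (12.2%), against 0.158%, 1.66% and 0.0395% of neutrophils. The T cells fell into a cluster marked by the gamma-delta receptor genes Trdc and Tcrg-V6 with Il17a (54 cells at day 10 and 2 at day 2) and one marked by Cd4, Cd40lg and Tnfrsf4 (44 and 9). At day 2 there were 11 T cells, too few for a comparison of genes between the days.

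Interferon gamma RNA (Ifng) was seen in NK and T cells. It had a UMI in 4 of 30 NK cells at day 2 (13.3%, interval 3.75% to 30.7%, median depth 2350 UMIs) and in 10 of 27 at day 10 (37.0%, interval 19.4% to 57.6%, median depth 4419 UMIs), and in 12 of 98 day 10 T cells (12.2%). Of day 10 neutrophils 0.0791% had one. Basophils were 38 cells at day 2 (19 each in mice 1 and 3, none in mice 2 and 4) and 1 at day 10. Under the 80% hashtag rule no cell was classed as a basophil on either day. At day 2 the type 2 cytokines Il4 and Il13 were seen in 11 and 6 of the 38 (28.9% and 15.8%), and in 0 of 4916 neutrophils, which allows a share of cells with a UMI of up to 0.061%. A single day 10 neutrophil barcode held 261 Il4 UMIs. No class other than neutrophils, monocytes and macrophages was tested for genes between the days.

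In neutrophils, 3 cytokine genes stood lower at day 10 without passing the edgeR test. Csf3, the granulocyte growth factor, was at 249 CPM over all day 2 neutrophils and 33.5 at day 10 (adjusted p = 0.0529), Tnf at 1185 and 494 (adjusted p = 0.0566), and the anti-inflammatory Il10 at 39.8 and 7.0 (adjusted p = 0.066).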
